A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

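Expression was measured with one-colour Affymetrix arrays that carry probe sets for S. cerevisiae and S. pombe, on total RNA from 12 cultures: 2 of a parental strain, 2 of an evolved strain and 1 each of 8 homozygotes derived from the evolved strain. The groups were taken from the strain names in the labels. The labels call the parental and evolved arrays biological replicates; the numbers of the homozygotes name strains. The evolved arrays differed less than any other pair (median absolute log2 difference 0.0583), so whether they are separate cultures is uncertain.

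The values used are the deposited intensity values, 1 per probe set and array, on a linear scale. Per the submitters' processing notes the tool was MAS5, with no version or role given; per the labels' protocols the target was biotin-labelled cRNA made from 100 ng of total RNA. The scaling between arrays is not given in the sources used here. The mean intensity over all probe sets after trimming 2% at each end lay between 448.9 and 454.9, so the arrays are close in scale but were not set to 1 common trimmed mean as they stand. The deposited intensities ran from about 4.05 to 12088, and the brightest genes lie near the upper end, where differences may be compressed. No detection calls were used here, and the array files before summarisation were not analysed here.

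Intensities were log2 transformed without a pseudocount (values under 1 would have been set to 1) and were not normalized again. Probe sets were named through the platform annotation, updated by gene identifier to the gene table of the R64 assembly. Of the probe sets, 5498 had 1 S. cerevisiae gene, 1746 had 1 gene of S. pombe, 1 had several genes, 213 were control or reporter probe sets and 3470 had no gene named here. Where a gene had several probe sets (47 genes), a gene-specific one was preferred to one marked as shared with related sequences, then the brightest. The array's own genome build is not given in the sources used here, so no coordinates are given; the R64 table was used for names, and chromosome and order along it were read from the systematic gene names. The background of an array was the 90th percentile of its S. pombe probe sets, and a gene was tested if it exceeded background on at least 2 arrays, which left 5352 of 5449 genes. The number of arrays limits the precision.

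The comparisons were fitted with limma 3.58.1 in R 4.3.3: 1 mean per group over all 12 arrays, so that the groups share 1 estimate of the spread per gene, with moderated variances that follow a trend in mean signal, and Benjamini-Hochberg adjustment over the 5352 genes at 0.05. Tests were two-sided. Spread among homozygotes was tested per gene as the variance of the 8 arrays over the squeezed variance of the parental and evolved duplicates (F test, upper tail, same adjustment). Because the groups share this estimate, the limma p-values of every comparison rest mostly on the spread between the 8 homozygotes, strains with 1 culture each. This includes evolved against parental arrays, where the 2 cultures of each group add less to the estimate. Array weights estimated for each group were 0.29 for parental arrays and 0.98 for homozygotes, which marks a wider spread between the parental arrays. SEs and p-values against parental arrays therefore understate the uncertainty, most of all for genes on which these 2 arrays differ. A fold change is the ratio of geometric means, and values after ± are SDs of signals or SEs of log2 changes.

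The 31 gene lists (yeast carbon metabolism, stress, nutrient regulons, ribosomes, and markers of haploid and sporulating cells) were fixed from textbook knowledge before the data were examined, as were the designs, the alternatives and the rule for naming genes. Lists were tested with limma's camera, at a preset correlation between genes of 0.01, for lists of at least 5 tested genes, and again with the correlation estimated from the data. With the estimated correlation 0 lists were called in any comparison, against 14, 16 and 9 with the preset one.

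Named genes are, for homozygotes against parental arrays, the 12 largest rises and 12 largest falls among called genes for which all homozygotes lay on the same side of both parental arrays; for evolved against parental arrays the 6 and 6 largest; for homozygotes against evolved arrays the 5 and 5 largest, of which there were none; and for the spread the 10 largest SDs past the threshold, of which there were none. Size was judged after signals under background were set to background. In each list up to 4 called members with the largest change could be named, and XKS1, GRE3, TAL1, TKL1, ZWF1 and GND1 were always named. A gene under background on all arrays of a group would have received only a bound.

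The code was tested on simulated data with 200 of 5352 genes changed. For homozygotes against parental arrays it recovered 77% of the genes changed by a log2 of 0.5, 98.5% at 1 and 100% at 2. For evolved against parental arrays it recovered 36%, 97.5% and 100%, and for homozygotes against evolved arrays 78%, 98.5% and 100%. For the spread it recovered 69% of genes whose SD was 4 times that of duplicates. These simulations gave all groups the same spread, which the real duplicates do not have.

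The numbers of the parental and evolved replicates were checked for pairing: deviations of parental 1 and evolved 1 from their group means had a correlation of -0.05 across genes, so the numbers were not treated as pairs. The alternatives were quantile normalization, median centring, no or a stricter background filter (95th percentile), a pseudocount of 16, flooring at background, variances without a trend, robust moderation, only the 2 groups compared, array weights for each group, every single-gene probe set, a 2-fold limit, each array left out in turn, the replicate number as a block, and the estimated correlation between genes. Chosen after seeing the data were a count without chromosome I genes, the spread against evolved duplicates alone, counts of genes and lists without homozygotes 5 and 6, the overlap of calls with 1 parental array given to each comparison, and a simulation of shared controls with unequal spread.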

Results

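Transcript levels were measured on 12 one-colour Affymetrix yeast arrays, each hybridised with biotin-labelled cRNA made from 100 ng of total RNA of 1 culture of Saccharomyces cerevisiae. All cultures were started at an optical density of 0.1 in medium with 4% xylose, a 5-carbon sugar that ordinary baker's yeast hardly uses, and were harvested after 25 h at 35 °C with shaking at 200 rpm. A parental strain (n = 2 cultures) was compared with an evolved strain (n = 2) and with homozygotes obtained from the evolved strain (n = 8, each a separate strain with 1 array). The design named the difference between the homozygotes and the parental strain as the one that bears on improved use of xylose.

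Of the probe sets, 5498 carried 1 S. cerevisiae gene, and 5352 genes exceeded background on at least 2 arrays and were tested. The background, set on each array by probe sets for the fission yeast S. pombe, lay between 18.7 and 19.6 intensity units, and the median S. cerevisiae gene was between 25.4 and 28.0 times as bright. The number of arrays limits the precision.

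The cultures of a strain differed to unlike degrees. The parental duplicates differed at least 2-fold in 102 genes, with a median absolute log2 difference of 0.22. The evolved duplicates differed 2-fold in 1 gene, with a median of 0.06, less than any of the 28 pairs of homozygotes (0.08 to 0.18). By this median the parental arrays were about as far from each other as from the other strains. Parental array 1 lay 0.19 to 0.28 from the evolved and homozygote arrays, and parental array 2 lay 0.18 to 0.27 from them. The count of genes differing 2-fold was higher for those pairs, at 114 to 302. The evolved arrays are labelled biological replicates, but whether they vary as separate cultures do could not be settled from the values. Every SD, test and array weight that uses them as n = 2 carries this doubt. Pairs of homozygotes differed 2-fold in 0 to 91 genes (median 12 over 28 pairs). The 16 rRNA control probe sets averaged 12.02 ± 0.01 on the log2 scale (SD, n = 2) in the parental arrays, 11.62 ± 0.04 (n = 2) in the evolved arrays and 11.67 ± 0.12 (n = 8) in the homozygotes. The difference of 0.36 between parental arrays and homozygotes had a two-sided exact permutation p = 0.0222, the smallest that 8 against 2 arrays allow. Homozygotes 5 and 6 lay nearest to the parental level, 0.13 and 0.21 below it. The 3' to 5' signal ratio of control transcripts, a measure of RNA integrity, was 1.32 ± 0.004 (SD, n = 2) on the log2 scale in parental arrays, 1.27 ± 0.008 (n = 2) in evolved arrays and 1.29 ± 0.08 (n = 8) in homozygotes. The exact permutation p against parental arrays was 0.578 for homozygotes and 0.333, the smallest possible, for evolved arrays.

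The first comparison asked how expression in the 8 homozygotes differed from that in the parental strain. Genes for vitamin B6 and thiamine synthesis and for sulfur assimilation were higher as lists in each of the 8 homozygotes. The iron regulon, a list that includes iron uptake genes, and STL1, for glycerol import, were lower. SNO1 and SNZ1 encode the subunits of a vitamin B6 synthesis complex. SNO1 rose 17.3-fold, from a signal of 63.6 ± 20.9 (SD, n = 2) to 1089 ± 209 (n = 8), a log2 change of 4.11 ± 0.20 (SE, adjusted p = 6.1e-08). SNZ1 rose 9.30-fold, from 594 ± 342 to 5058 ± 378 (log2 change 3.22 ± 0.20, adjusted p = 4.8e-07). Its change was 2.59 without parental array 1 and 3.84 without parental array 2. The SE, taken from the spread shared by all groups, does not reflect this distance between the parental arrays. The largest fall was that of STL1, the glycerol proton symporter, from 750 ± 88.4 to 81.3 ± 13.5 (log2 change -3.22 ± 0.16, adjusted p = 6.1e-08).

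In this comparison limma called 1669 of 5352 genes at an adjusted p under 0.05, 708 higher and 961 lower in homozygotes. Of these, 65 were at least 2-fold higher and 79 at least 2-fold lower, and the median log2 change of all genes was -0.04. After median centring the counts were 839 higher and 834 lower, and after quantile normalization 751 and 816, so the excess of lower genes depended on the scaling. Over all 5352 genes, called or not, the homozygotes and the parental arrays did not overlap in 1672, where chance gives 4.44% of genes.

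The other large rises were those of THI4, a thiamine thiazole synthase, with a log2 change of 3.38 ± 0.42, YPS6, a cell surface protease, with 2.96 ± 0.19, STR3, a cystathionine beta-lyase, with 2.54 ± 0.48, and YCT1, a cysteine transporter, with 2.37 ± 0.33. BNA2, the first enzyme of NAD synthesis from tryptophan, changed by 2.33 ± 0.24, THI13 by 2.23 ± 0.19, MET2 by 1.97 ± 0.14 and MET32 by 1.92 ± 0.20. The rises of YDR261C-D with 2.05 ± 0.45 and YDR261W-B with 1.92 ± 0.32 came, like that of THI13 from probe sets that can also detect close relatives of the gene, so the gene itself is uncertain. The rise of YDR261C-D was not past the threshold without parental array 1 (1.43, adjusted p = 0.077).

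Among the falls, LYS9, of lysine synthesis, changed by -1.69 ± 0.15, SSA4, a heat-inducible chaperone, by -1.54 ± 0.27, and ICL1, the isocitrate lyase of the glyoxylate cycle, by -1.52 ± 0.41. OPI10 changed by -1.64 ± 0.35, LTE1 by -1.52 ± 0.17 and SPO22 by -1.51 ± 0.23. The SPO22 signal was 19.1 in homozygote 3 and 27.7 to 38.6 in the other homozygotes, near the background of 18.7 to 19.6. The size of its fall is therefore uncertain. Without parental array 1 the fall of OPI10 was -0.73 (adjusted p = 0.0744), and without parental array 2 that of ICL1 was -1.33 (adjusted p = 0.0905), neither past the threshold. SSA4 was at 1983 in parental array 1 and 675 in parental array 2, and its change was -0.76 without the former and -2.31 without the latter.

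**Figure D1:**
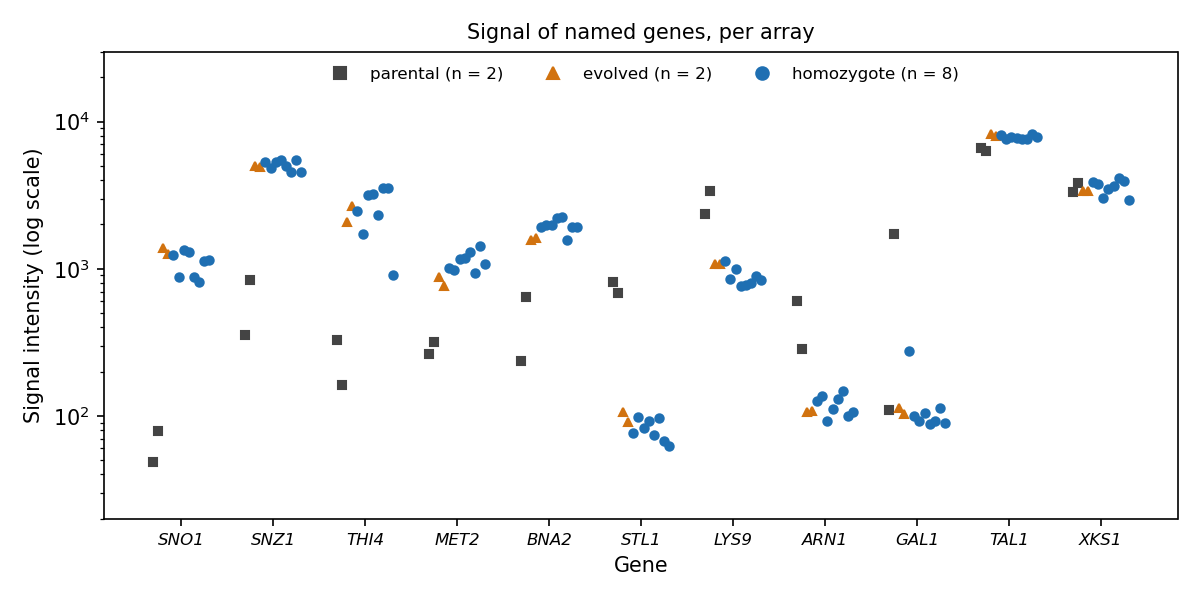
Signal intensity (vertical axis, log scale) of 11 named genes (horizontal axis) on each array, with squares for the 2 parental, triangles for the 2 evolved and circles for the 8 homozygote arrays. SNO1 was between 811 and 1347 in the homozygotes against 48.8 and 78.3 in the parental arrays, XKS1 overlapped between groups, and GAL1 was high in 1 parental array alone, at 1711.

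Of 27 measured genes of the sulfur and methionine list, 23 rose and 1 fell (also 23 and 1 when adjusted over the list alone), with a median log2 change of 1.04 and a camera adjusted p = 5.1e-17. STR3, YCT1, MET2 and MET32 changed most. Of 18 genes of thiamine and vitamin B6 synthesis, 12 rose and none fell (13 when adjusted over the list alone; median 0.74, adjusted p = 5.6e-10). Both lists had an adjusted p = 0.271 with an estimated correlation between genes. The rRNA probe sets were 0.36 lower on the log2 scale in the same homozygote arrays.

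The iron regulon, a list that includes genes of iron uptake, moved the other way. Of its 31 genes 18 fell and 2, ISU2 and BIO2, rose (the same counts when adjusted over the list alone). The median was -0.70 and the camera adjusted p = 0.0001 (adjusted p = 0.699 with an estimated correlation). The siderophore transporter genes ARN1, SIT1 and ARN2 changed by -1.83 ± 0.22, -1.79 ± 0.40 and -1.60 ± 0.32, the cell wall mannoprotein gene FIT2 by -1.75 ± 0.48 and the reductase gene FRE2 by -1.53 ± 0.20. Without parental array 1, ARN2 (-0.77, adjusted p = 0.0568) and FIT2 (-1.54, adjusted p = 0.102) were not past the threshold.

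Of 38 genes of the respiratory chain and ATP synthase, 15 rose and none fell (18 when adjusted over the list alone; median 0.14, adjusted p = 1.4e-06), among them COX5B with 0.64 ± 0.13 (0.32 without parental array 2) and COX7 with 0.48 ± 0.08 (0.29 without parental array 1). Of 70 mitochondrial ribosomal protein genes, 26 fell and 4 rose (28 and 4 when adjusted over the list alone; median -0.16, adjusted p = 0.0111), among them MRPL20 with -0.78 ± 0.12 and MRPS5 with -0.61 ± 0.10. Both lists had an adjusted p = 0.699 with an estimated correlation. The respiratory list was not called without parental array 1, where its mean went from 0.17 to 0.07. The mitochondrial ribosomal list was not called without parental array 2, where its mean went from -0.16 to -0.09.

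Among lists of carbon metabolism, the glyoxylate cycle and gluconeogenesis had 6 falls and 2 rises among 16 genes (the same counts when adjusted over the list alone; adjusted p = 0.0499), with ICL1 at -1.52 ± 0.41. YAT1, a carnitine acetyltransferase (-1.25 ± 0.10), and ACS1 are among these falls and lie on chromosome I, where 66 of 81 genes fell and 3 rose (median -0.81). Peroxisome and fatty acid oxidation genes had 7 falls and 2 rises among 20 (the same when adjusted over the list alone; adjusted p = 0.0499), among them OAF1, a regulator of that pathway (-1.16 ± 0.10), which also lies on chromosome I. Neither list was called without parental array 2, nor was ICL1 (-1.33). There the mean of the glyoxylate list went from -0.46 to -0.23, while that of the peroxisome list went only from -0.24 to -0.21. The glyoxylate list, which is close to the threshold, also missed it without homozygote 1, 2, 3, 4 or 8 (adjusted p from 0.0544 to 0.0827), and the peroxisome list without homozygote 1, 5, 7 or 8 (0.0516 to 0.069) and after quantile normalization (0.0903). Both missed it with a stricter (0.054) or floored background (0.0546). With an estimated correlation the adjusted p was 0.874 and 0.699 for these lists. In the tricarboxylic acid cycle 4 of 18 genes rose and 1 fell (1 and 0 when adjusted over the list alone; adjusted p = 0.0209), with PYC2, pyruvate carboxylase, at 0.33 ± 0.07. In glycolysis 4 of 17 rose and 1 fell (the same when adjusted over the list alone; adjusted p = 0.0471), the fall being that of HXK2, hexokinase 2, with -0.95 ± 0.13. Both had an adjusted p = 0.862 with an estimated correlation and were not called without parental array 1 (adjusted p = 0.412 and 0.837) or after quantile normalization (adjusted p = 0.194 and 0.833), and glycolysis also not without homozygote 1, 6 or 7 (0.057 to 0.0685) or with a stricter (0.0509) or floored background (0.0518). The mean of the tricarboxylic acid list turned from 0.14 to -0.07, and that of glycolysis from 0.02 to -0.06, without parental array 1.

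Of 9 galactose genes 5 fell and none rose (the same when adjusted over the list alone; adjusted p = 0.0358, and adjusted p = 0.699 with an estimated correlation). These calls rested on 1 array. GAL1 was at 109 in parental array 1 and 1711 in parental array 2, against 120 ± 63.4 (SD, n = 8) in homozygotes, and GAL7 was at 184 and 1540 against 108 ± 36.3. Without parental array 2 the list was not called (adjusted p = 0.489), and the log2 change of GAL1 went from -1.96 ± 0.69 (adjusted p = 0.0435) to 0.024. GAL1 also missed the threshold without either evolved array (adjusted p = 0.0575) and without any of homozygotes 2 to 8 (0.0585 to 0.0651).

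Rises were called in 4 further lists. Cytosolic ribosomal protein genes had 20 rises and 6 falls among 127 (8 and 2 when adjusted over the list alone; median 0.05, adjusted p = 0.0031), whose test turned downwards after quantile normalization (mean 0.012, adjusted p = 0.834). Oxidative stress genes had 11 rises and 3 falls among 29 (12 and 3 when adjusted over the list alone; adjusted p = 0.0076), led by OYE3, a dehydrogenase, with 1.45 ± 0.29, which without parental array 1 was at 0.68 (adjusted p = 0.0538). SRX1, sulfiredoxin, changed by 0.86 ± 0.10. The phosphate regulon had 8 rises and 2 falls among 18 (8 and 3 when adjusted over the list alone; adjusted p = 0.0111), with the transporter gene PHO84 at 1.54 ± 0.28 (0.86 without parental array 2) and SPL2 at 1.47 ± 0.22. Hypoxic and anaerobic genes had 7 rises and no falls among 22 (the same when adjusted over the list alone; adjusted p = 0.0445), with ANB1 at 0.77 ± 0.15 (0.48 without parental array 2). With an estimated correlation the adjusted p of these lists was 0.874, 0.699, 0.699 and 0.271. The oxidative stress list was not called without parental array 1, where its mean went from 0.16 to -0.01 (adjusted p = 0.455), or after quantile normalization (0.0502), and the phosphate and hypoxic lists were not called without parental array 2 (adjusted p = 0.145 and 0.146). The hypoxic list also missed it without homozygote 1 (0.0584), after median centring (0.0525) and with a stricter (0.0652) or floored background (0.0628). It missed it too without both homozygotes 5 and 6 (0.0565), as did glycolysis (0.0812).

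None of the 3 lists next to the use of xylose was called. Of 9 genes of xylose and polyol metabolism 1 rose and 1 fell (adjusted p = 0.525), SOR2, a sorbitol dehydrogenase whose probe set can also detect a near-identical gene, with 1.21 ± 0.11, and GRE3, an aldose reductase that can reduce xylose, with -0.38 ± 0.11, which without parental array 2 was at -0.21 (adjusted p = 0.262). XKS1, xylulokinase, had a signal of 3575 ± 341 (SD, n = 2) in parental arrays and 3602 ± 424 (n = 8) in homozygotes (log2 change 0.01 ± 0.11, adjusted p = 0.976). In the pentose phosphate pathway 3 of 12 genes rose and 2 fell (adjusted p = 0.918). TAL1, transaldolase, rose by 0.28 ± 0.03 (adjusted p = 7.8e-05) and TKL2, the minor transketolase, changed by -1.45 ± 0.14. ZWF1 was at 0.28 ± 0.10 (adjusted p = 0.041), and at 0.09 without parental array 1 (adjusted p = 0.559); it also missed the threshold without either evolved array (0.0539 and 0.0541) and without homozygote 1, 2, 4, 6 or 7 (0.0557 to 0.064). TKL1 was at -0.09 ± 0.05 (adjusted p = 0.178), past the threshold only after quantile normalization (-0.14, adjusted p = 0.0431), and GND1 at 0.06 ± 0.09 (adjusted p = 0.628). Of 12 tested hexose transporter genes, the carriers by which xylose also enters yeast, 3 rose and 6 fell (median -0.48, adjusted p = 0.520). Most tested members thus changed, in both directions. The list had 18 members, and the rest were not tested, so the result does not cover all of them. The list mean was below the mean of the parental arrays in all 8 homozygotes (-0.60 to -0.07), although homozygote 6 (8.34) was level with parental array 1 (8.33). Among the members were GAL2, whose fall was lost without parental array 2 (-0.43, adjusted p = 0.180), and HXT15, from a shared probe set, at 1.03 ± 0.18 (0.58 without parental array 2), and HXT5 at -1.29 ± 0.23. TAL1 is among the brightest probe sets, where signals may be compressed, which was not tested.

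The remaining lists had no call with all arrays. Rises and falls were 3 and 6 of 24 for glucose sensing and repression, 6 and 6 of 23 for ethanol, acetate and glycerol metabolism, 1 and 0 of 18 for trehalose and glycogen, 3 and 10 of 29 for heat shock and chaperones, 2 and 0 of 6 for maltose and sucrose metabolism, 4 and 7 of 16 for arginine and lysine synthesis, and 12 and 9 of 49 for other amino acid synthesis. They were 3 and 3 of 26 for nitrogen catabolite repressed genes, 5 and 3 of 27 for ergosterol synthesis, 2 and 4 of 75 for ribosome biogenesis, 3 and 3 of 13 for flocculation and adhesion, and 2 and 6 of 29 for the cell cycle. The lists of other cell states, mating and haploid-specific genes (2 and 2 of 22) and meiosis and sporulation (2 and 3 of 29), were not called either. Only 6 of the 14 members of the maltose and sucrose list were tested. Adjusted over the list alone, the counts differed for ethanol, acetate and glycerol (6 and 8), heat shock (4 and 11), maltose (3 and 0), other amino acids (14 and 11), ergosterol (7 and 3), ribosome biogenesis (0 and 1) and sporulation (1 and 0). The median and the mean differed in sign for ethanol, acetate and glycerol (0.12 and -0.08), flocculation (0.07 and -0.03) and the cell cycle (0.05 and -0.09). Without parental array 2 the maltose (mean 0.46, adjusted p = 0.0306) and other amino acid lists (0.24, adjusted p = 9.8e-05) passed. Without parental array 1 the arginine and lysine list passed (-0.37, adjusted p = 0.0455), and without homozygote 3 the maltose list (0.34, adjusted p = 0.0461). After quantile normalization the heat shock list passed (-0.32, adjusted p = 0.0187). Single genes in these lists with large changes included PDC6, a minor pyruvate decarboxylase, with 1.53 ± 0.11, ARG3 with 1.86 ± 0.25 and CLN3, a G1 cyclin gene on chromosome I, with -1.18 ± 0.08. In the arginine and lysine list the 4 rises were those of ARG3, ARG1, ARG8 and CPA1. The 7 falls were those of LYS1, LYS2, LYS9, LYS12, LYS20, ARG2 and ARG7, so the list joins genes that moved in opposite directions.

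When genes were grouped by chromosome, a grouping chosen after the values were seen, those of chromosome I stood apart. Of its 81 genes tested, 66 fell and 3 rose in homozygotes, with a median log2 change of -0.81 and a camera adjusted p = 2.8e-28 over 16 chromosomes (adjusted p = 0.000146 with an estimated correlation). Among the rises, YAR009C (1.82) and YAR010C (0.96) came from probe sets that can also detect close relatives of the gene. The medians of the other 15 chromosomes lay between -0.07 and 0.02. Medians along the chromosome, from the end of the left arm to that of the right arm in 4 groups of 20 or 21 neighbouring genes, were -0.83, -1.01, -0.75 and -0.69. Chromosome I held 66 of the 961 lower genes and 22 of the 79 that were at least 2-fold lower, among them LTE1 and CLN3.

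**Figure D2:**
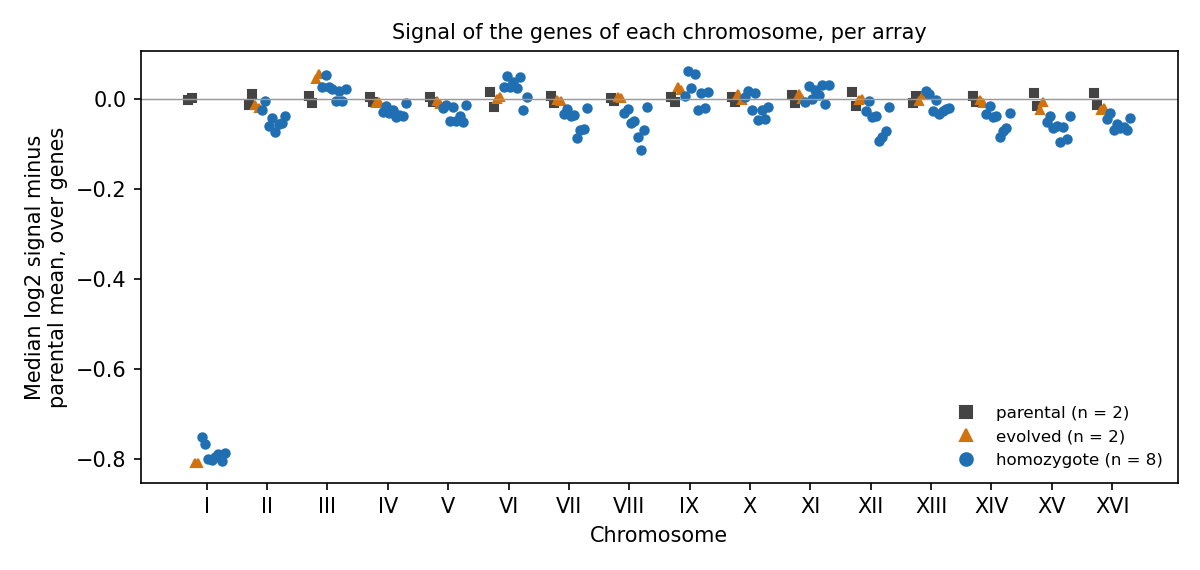
Median over the genes of each chromosome (horizontal axis, I to XVI) of the log2 signal minus the mean of the parental arrays (vertical axis), with 1 point per array (squares parental, triangles evolved, circles homozygote). On chromosome I all 10 evolved and homozygote arrays lie between -0.81 and -0.75, and on the other 15 chromosomes the medians of homozygotes minus parental arrays are between -0.07 and 0.02.

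The number of genes called between homozygotes and parental arrays depended on how the spread was shared. With array weights estimated for each group, which give the parental arrays a weight of 0.29 against 0.98 for homozygotes, 325 genes were called, all of them among the 1669 and in the same direction, and STR3, YDR261C-D, SIT1, FIT2, ICL1, HXT5, GRE3, ZWF1, PYC2, ANB1 and GAL1 were not. Of the 1669 genes, 618 were also called in the same direction without parental array 1 and without parental array 2.

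The second comparison asked how the evolved strain, from which the homozygotes came, differed from the parental strain. The vitamin genes again had the largest rises and STL1 the largest fall. SNO1 rose from 63.6 ± 20.9 (SD, n = 2) to 1318 ± 86.2 (n = 2), a log2 change of 4.41 ± 0.26 (SE, adjusted p = 8.7e-07). THI4 changed by 3.36 ± 0.53, SNZ1 by 3.18 ± 0.26, YPS6, the cell surface protease, by 3.0 ± 0.24, THI13 by 2.14 ± 0.24 and BNA2 by 2.03 ± 0.31 (1.31 without parental array 1). STL1 fell from 750 ± 88.4 to 98.5 ± 10.4, a log2 change of -2.93 ± 0.21 (adjusted p = 2.9e-06). SIT1 changed by -2.60 ± 0.50, FIT2 by -2.48 ± 0.61 and ICL1 by -2.20 ± 0.52.

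Limma called 450 genes, 171 higher and 279 lower in the evolved strain, of which 38 and 59 changed at least 2-fold. Over all 5352 genes, called or not, the evolved and the parental arrays did not overlap in 2773, where chance gives 33.3% of genes. GAL7 (-2.65 ± 0.67) and GAL2 (-2.45 ± 0.71) were also among the 6 largest falls, and both were lost without parental array 2 (-1.12 with adjusted p = 0.0729, and -0.71 with adjusted p = 0.0937). GAL7, GAL2, FIT2 and ICL1 were also lost without evolved array 1 (adjusted p from 0.125 to 0.215) and without evolved array 2 (0.112 to 0.197), and GAL2, near the threshold, without any single homozygote (0.0567 to 0.0675). ICL1 was lost without parental array 2 (-2.01, adjusted p = 0.0532), FIT2 without parental array 1 (-2.27, adjusted p = 0.0785), and SIT1 without evolved array 2 (-2.50, adjusted p = 0.0574). From the 4 arrays of these groups alone SNZ1 (adjusted p = 0.0562), BNA2 (0.166), GAL7 and GAL2 were not called by limma. GAL7 and GAL2 were also lost with the replicate number as a block, and FIT2 and ICL1 with array weights for each group. GAL2 was lost too after quantile normalization or median centring, with a pseudocount of 16, without a variance trend and with robust moderation.

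Of the sulfur and methionine list 17 of 27 genes rose and none fell (19 when adjusted over the list alone; median 0.82, adjusted p = 5.7e-17), with MET6, methionine synthase, at 1.83 ± 0.12 and MET3 at 1.70 ± 0.18. Of the thiamine and vitamin B6 list 10 of 18 rose and none fell (12 when adjusted over the list alone; adjusted p = 2.5e-12). The rRNA probe sets were 0.40 lower on the log2 scale in the evolved arrays (exact permutation p = 0.333, the smallest that 2 against 2 arrays allow). The iron regulon had 15 falls and 1 rise among 31 genes (17 and 2 when adjusted over the list alone; adjusted p = 9.0e-09), and mitochondrial ribosomal proteins 20 falls and no rise among 70 (33 and 1 when adjusted over the list alone; adjusted p = 1.2e-10). The glyoxylate cycle and gluconeogenesis had 5 falls and no rise among 16 (12 and 0 when adjusted over the list alone; adjusted p = 2.2e-05), and peroxisome and fatty acid oxidation 5 falls and 1 rise among 20 (10 and 1 when adjusted over the list alone; adjusted p = 0.0011). Ribosome biogenesis genes were shifted upwards as a list (median 0.15, 64 of 75 higher, 1 called; adjusted p = 5.8e-05), although not without parental array 2 (adjusted p = 0.147). With an estimated correlation the adjusted p of these lists was 0.139, 0.095, 0.139, 0.139, 0.537, 0.139 and 0.666, in the order given.

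In all, 16 of the 31 lists were called, 10 upwards and 6 downwards, and none with an estimated correlation. The others called upwards were cytosolic ribosomal proteins (3 of 127 rose, 0 when adjusted over the list alone), hypoxic and anaerobic genes (3 of 22, and 5), other amino acid synthesis (7 rose and 1 fell of 49, and 9 and 1), ergosterol synthesis (4 and 1 of 27, and 10 and 1), oxidative stress defence (5 of 29, and 5), the respiratory chain (0 of 38, and 0), and maltose and sucrose metabolism (2 of 6, and 3). Those called downwards were the galactose list (3 of 9 fell, and 3) and heat shock (5 fell and 1 rose of 29, and 9 and 2). With an estimated correlation the adjusted p was 0.095 for the hypoxic list, 0.666 for cytosolic ribosomal proteins, other amino acids and the respiratory chain, and 0.537 for the other 5. After quantile normalization the calls of cytosolic ribosomal proteins (adjusted p = 0.165), the respiratory chain (0.4997) and ergosterol synthesis (0.0545) were lost, and without a background filter that of maltose (0.0629). The upward calls of oxidative stress (adjusted p = 0.577), the respiratory chain (0.657), other amino acid synthesis (0.986) and maltose and sucrose metabolism (0.137) were lost without parental array 1, and the galactose call without parental array 2 (adjusted p = 0.404). Without parental array 1 the mean of the respiratory list went from 0.09 to -0.0089, that of oxidative stress from 0.16 to -0.01 and that of other amino acids from 0.15 to -0.005. The tricarboxylic acid list, not called with all arrays (adjusted p = 0.312), was called downwards without parental array 1 (mean -0.15, adjusted p = 0.0063) and upwards without parental array 2 (0.28, adjusted p = 9.5e-07). Other lists that passed only without 1 array were glycolysis without parental array 2 (0.12, adjusted p = 0.0026) or evolved array 2 (0.0364), and the pentose phosphate pathway without parental array 2 (0.049). Without parental array 1 those were arginine and lysine synthesis (-0.34, adjusted p = 0.0154) and ethanol, acetate and glycerol metabolism (-0.28, adjusted p = 0.0424). The phosphate regulon (adjusted p = 0.0537) passed without parental array 1 (0.0101), evolved array 1 (0.0094), homozygote 2 (0.036) or homozygote 7 (0.0275), and with the replicate number as a block (0.0196), where 154 genes were called in all. Of 81 chromosome I genes 63 fell and none rose, with a median of -0.81 (adjusted p = 1.4e-44, and adjusted p = 2.1e-05 with an estimated correlation), while the medians of the other 15 chromosomes lay between -0.02 and 0.05.

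TAL1 rose by 0.33 ± 0.04 (adjusted p = 0.000352, and 0.0641 from the 4 arrays of these groups alone). XKS1 was at -0.08 ± 0.14 (adjusted p = 0.788), GRE3 at -0.29 ± 0.14 (adjusted p = 0.244), TKL1 at 0.12 ± 0.06 (adjusted p = 0.250), ZWF1 at 0.35 ± 0.12 (adjusted p = 0.093) and GND1 at 0.22 ± 0.12 (adjusted p = 0.267). Without parental array 2, ZWF1 (0.54, adjusted p = 0.007) and GND1 (0.38, adjusted p = 0.0482) were past the threshold.

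Calls of the first and second comparison overlapped. Of the genes called, 165 were higher in both and 259 lower in both, and 0 were called in opposite directions; independent lists of these sizes would share 22.6 and 50.1. Both comparisons use the same 2 parental arrays, and unchanged groups simulated against shared controls gave a correlation of log2 changes of 0.63 with equal spread in all groups, and of 0.93 with the unequal spread that the array weights give, a simulation chosen after seeing the data. The observed 0.87 lies between them, so the correlation by itself does not show a shared change. The observed covariance of 0.119 was above both simulated values, 0.0127 and 0.0433. With 1 parental array given to each comparison, a split chosen after seeing the data, the covariance was 0.0752 (homozygotes against parental array 1, evolved against parental array 2) or 0.0832 (the reverse). The correlation across genes was 0.42 or 0.48; using 1 parental array in place of 2 also lowers it, so its drop does not measure the effect of sharing alone. In the first split 108 genes were higher in both, 163 lower in both and 19 opposite, where independent lists would share 32.1, 58.1 and 86.6. In the reverse these were 140, 187 and 38, against 47.9, 65.8 and 112.3. Each single parental array was assumed to vary like the other groups, and genes are not independent replicates. The count of 450 depended on the arrays and weights in the fit: 46 genes were called from the 4 parental and evolved arrays alone, 184 with array weights for each group, and 118 or 153 when 1 evolved array was left out, while without parental array 2 it was 863.

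**Figure D3:**
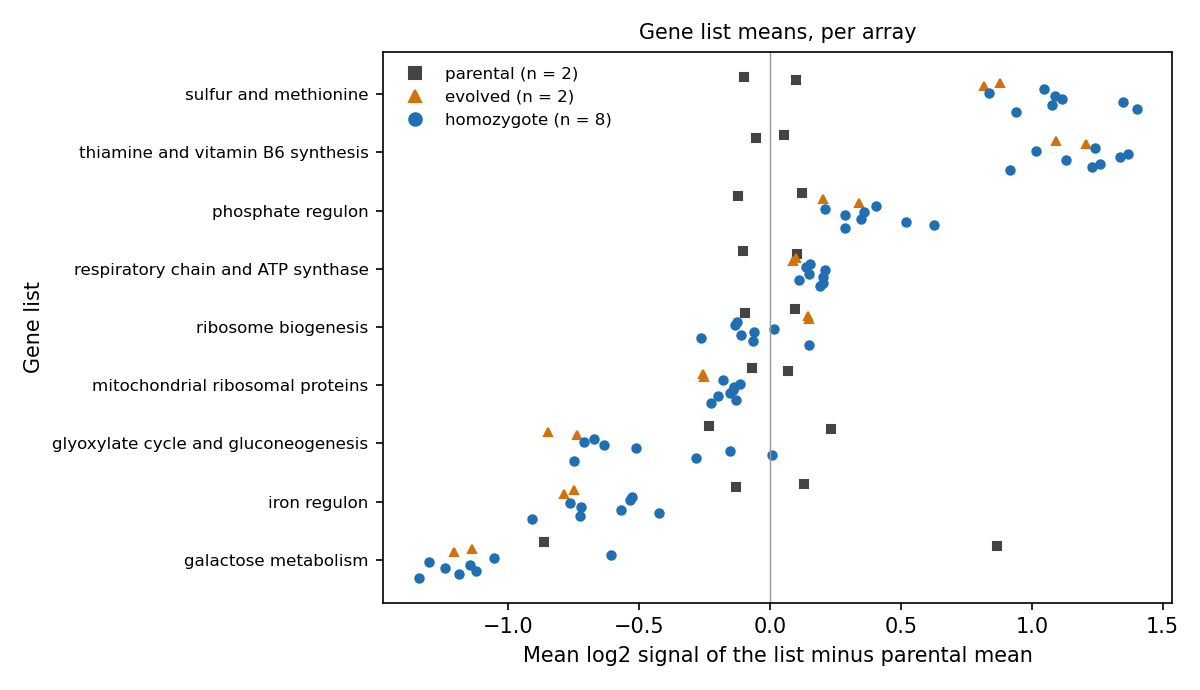
For 9 gene lists (vertical axis), the mean log2 signal minus the mean of the parental arrays (horizontal axis), with 1 point per array (squares parental, triangles evolved, circles homozygote). The mean changes of homozygotes were 1.11 for the sulfur list and -0.65 for the iron regulon, and the 2 parental arrays lie farthest apart on the galactose list.

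The third comparison asked whether the homozygotes as a group differed from the evolved strain they came from. Limma called 0 genes, and the smallest adjusted p was 0.137. An unadjusted limma p under 0.05 was found for 929 genes, where chance gives 267.6. Over all 5352 genes, called or not, the homozygotes and the evolved arrays did not overlap in 1178, where chance gives 4.44% of genes. So 0 calls do not show that the groups were the same. These counts carry the doubt about the evolved arrays as separate cultures. Ribosome biogenesis genes were lower as a list (median log2 change -0.23, 5 of 75 higher, none called and 11 lower when adjusted over the list alone; camera adjusted p = 3.2e-13). Homozygote 8 did not share this shift, with a list mean of 10.59 against 10.58 and 10.59 in the evolved arrays, and homozygote 6 was lowest at 10.17. Lists shifted upwards were mitochondrial ribosomal proteins (median 0.09, 55 of 70 higher; adjusted p = 6.4e-07), the respiratory chain and ATP synthase (0.07, 32 of 38 higher; adjusted p = 4.7e-05), the glyoxylate cycle and gluconeogenesis (0.26, 14 of 16 higher; adjusted p = 0.0015), sulfur and methionine (0.18, 18 of 27 higher, 6 higher when adjusted over the list alone; adjusted p = 0.0022), trehalose and glycogen (0.14, 14 of 18 higher; adjusted p = 0.0051) and the tricarboxylic acid cycle (0.08, 14 of 18 higher; adjusted p = 0.0183). The pentose phosphate pathway (-0.16, 1 of 12 higher; adjusted p = 0.0135) and ergosterol synthesis (-0.11, 6 of 27 higher; adjusted p = 0.0135) were shifted downwards, the latter not without evolved array 1 (adjusted p = 0.124). With an estimated correlation the adjusted p was 0.791 for the tricarboxylic acid cycle, which also missed the threshold after quantile normalization (adjusted p = 0.0508), and 0.729 for each of the other 8 lists. The glyoxylate list was highest in homozygotes 6, 5 and 7 (mean log2 signal 9.86, 9.71 and 9.57, against 9.11 to 9.35 in the other 5 and 9.01 and 9.12 in evolved arrays). Homozygotes 5 and 6 also had the rRNA signal nearest to the parental arrays, and without both, an alternative chosen after seeing the data, the list mean went from 0.33 to 0.20 (adjusted p = 0.0107). Lists that passed only under an alternative were cytosolic ribosomal proteins, downwards, after quantile normalization (adjusted p = 0.0044), without evolved array 2 (0.0124) or without homozygote 5 (0.0351). Other amino acid synthesis passed downwards after quantile normalization (0.0419), without parental array 1 or 2 (0.0443 and 0.0449) or without homozygote 7 (0.0228). Without evolved array 2 the nitrogen (0.0363), phosphate (0.0124) and peroxisome lists (0.0318) passed upwards as well, 13 lists in all against 9. Without homozygote 8 the iron regulon passed (0.0248).

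The always-named genes did not pass the threshold, with log2 changes of 0.08 ± 0.11 for XKS1 (adjusted p = 0.739), -0.09 ± 0.11 for GRE3 (0.699), -0.05 ± 0.03 for TAL1 (0.450), -0.20 ± 0.05 for TKL1 (0.163), -0.07 ± 0.10 for ZWF1 (0.734) and -0.16 ± 0.09 for GND1 (0.384). The count of 0 depended on the weights given to the arrays. With array weights for each group, which change all 3 groups at once (parental 0.29, evolved 3.69, homozygote 0.98), 1549 genes were called (669 higher and 880 lower in homozygotes), TKL1 and GND1 among them, and without homozygote 8 the shared estimate called 29, against 1 without either parental array.

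The fourth comparison asked which genes varied more among the 8 homozygotes than between duplicate cultures. No gene passed the F test with limma's squeezed variances; 120 genes had an unadjusted p under 0.05, where chance gives 267.6. The largest SDs of log2 signal were those of YOR387C, with signals from 54.3 to 811 among homozygotes, ADH4, an alcohol dehydrogenase, from 1439 to 8940, YNL194C, from 53.7 to 365, FIT2, from 422 to 1966, and ADY2, an acetate transporter, from 176 to 637, genes named by the size of their SD after no gene had passed. YOR387C was at 3916 and 103 in the parental duplicates. The result rested on the parental duplicates: with the evolved duplicates alone as the error, an alternative chosen after seeing the data, 3405 genes passed. Leaving out either parental array also leaves the evolved duplicates as the only error, so it is no separate test.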

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

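All tests of explanations in this part were chosen after the results had been seen.

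Genes of chromosome I were lower in every evolved and homozygote array than in the parental arrays, with a median log2 change of -0.81. After quantile normalization chromosome I still lay 0.77 below the other genes (difference of medians -0.77). This does not test scaling of the arrays, because such a step treats genes of all chromosomes alike and could hardly remove the gap. For the same reason a scaling factor for a whole array cannot set 1 chromosome apart. A single aberrant parental array is argued against by a median of -0.80 without parental array 1 and -0.83 without parental array 2. A different number of chromosome I copies would lower all parts of the chromosome, and the part nearest to 0, the 20 genes at the end of the right arm in the evolved arrays, had a median of -0.53. Some of these genes have probe sets that can also detect close relatives. In the evolved arrays they were YAR009C (0.87), YAR010C (0.86), YAR064W (0.32), PAU7 (0.16), PHO11 (0.08) and YAR066W (-0.29). All of them lie above the median of -0.53 and pull it towards 0. A step from 3 copies to 2 corresponds to -0.58 on the log2 scale and one from 2 to 1 to -1. The values are consistent with such a difference, a hypothesis, but no DNA was measured, and a gain in the parental cultures and a loss in the evolved strain would give the same ratios.

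The fall of the galactose genes rested for the most part on 1 parental array. Without parental array 2 the mean log2 change of the list went from -1.13 to -0.26 in homozygotes and from -1.17 to -0.31 in the evolved strain, neither past the threshold (adjusted p = 0.489 and 0.404), and what remains is not accounted for by that array. Parental array 1 had a list mean of 8.24, within the range of the homozygotes, but an evolved or homozygote culture under its label is argued against, since its chromosome I genes differed from those of parental array 2 by a median of -0.0045, where all evolved and homozygote arrays lay at -0.75 or lower against the parental mean. Whether the culture itself differed, for example in its medium, was not tested. Among homozygotes, homozygote 1 was apart from the others on the same list, with a mean log2 signal of 8.50 against 7.77 to 8.05 (gap over range 0.61).

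Sulfur and vitamin genes were higher in the evolved strain and homozygotes, whose rRNA probe sets were lower. Across the 8 homozygotes the sulfur list mean went up with the rRNA signal, so that the slope times the rRNA gap gave a change of -0.24, against an observed rise of 1.11; with each homozygote left out it was between -0.37 and -0.03. For the thiamine and vitamin B6 list the slope gave -0.07 against 1.19, and between -0.29 and 0.03 with each homozygote left out. Taken from the homozygotes, the rRNA slope therefore gave no rise of this size. Their rRNA means (11.58 to 11.90) did not reach the parental 12.02, so the slope is extrapolated. An RNA difference that acts otherwise between strains cannot be excluded by it. A single parental array is argued against by mean rises of 1.01 or more without either (sulfur list, without parental array 1). A difference in growth stage or nutrient supply at 25 h between cultures, and a difference inherited by the strains, may both produce it; neither was tested.

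Other splits of the arrays were counted for the comparison of homozygotes with parental arrays, in fits of these 10 arrays alone, which called 1474 genes against 1669 with the evolved arrays in the fit. Of the 45 ways to part these 10 arrays into 8 and 2, 1 split, the real one, gave as many genes. The highest of the others gave 10 (parental array 1 with homozygote 8). The homozygotes come from 1 evolved strain, so the arrays are not exchangeable. Every other split puts parental and homozygote arrays in the same group, which widens the spread within groups and lowers the count. The splits therefore cannot exclude chance, nor tell a difference of strains from one of cultures.

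Among 63 groups of 8 homozygote values tested for a sample far from the others (31 list means, 30 genes and 2 array measures), 5 were found, where chance gives about 1 in 20 or 3.15. Besides the galactose list, the hexose transporter list was higher in homozygote 6 (mean log2 8.34 against 7.81 to 8.05, gap over range 0.536). The hypoxic and anaerobic list was also higher in homozygote 6 (9.03 against 8.87 to 8.93, 0.645). BNA2 was lower in homozygote 6 (signal 1578 against 1924 to 2252, 0.558), and SPO22 was lower in homozygote 3 (19.1 against 27.7 to 38.6, 0.528). The SPO22 signal in homozygote 3 was under the background of that array, 19.6, so 1 of the 5 does not rest on a signal above background.

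Reporter probe sets and probe sets with no gene named here were outside the comparisons. Of 703 such probe sets above background, 41 were higher and 27 lower in homozygotes than in parental arrays, the largest log2 rise being 1.41 ± 0.13 (SE).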

How the results depend on the processing

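The settings "without chromosome I genes", "evolved duplicates alone as error" and "without homozygotes 5 and 6" were chosen after seeing the data. The sulfur, thiamine and vitamin B6, and iron lists kept their direction and call against parental arrays under every setting in which lists were tested, except 1. That was the estimated correlation, with which 0 lists were called in each of the 3 comparisons (against 14, 16 and 9). Lists were not tested with array weights, only the groups compared, variances without a trend or robust moderation. Nor were they tested with every single-gene probe set, a 2-fold limit or without chromosome I genes. Signal over background was between 25.4 and 28.0, and the number of arrays limits the precision. Higher and lower calls in homozygotes went from 708 and 961 to 839 and 834 with median centring. Of genes called between homozygotes and parental arrays (1669), array weights for each group left 325 and a 2-fold limit 144; leaving out single arrays gave 1394 to 1677, leaving out chromosome I genes 1579, and leaving out homozygotes 5 and 6 1433 (12 lists). Between evolved and parental arrays (450) weights gave 184, a 2-fold limit 97, only the groups compared 46, the replicate number as a block 154, single arrays left out 118 to 863, and chromosome I genes left out 344. Between homozygotes and evolved arrays (0) weights gave 1549, only the groups compared 1, single arrays left out 0 to 29, and homozygotes 5 and 6 left out 0 (9 lists). For the spread among homozygotes (0), evolved duplicates alone as error gave 3405 and single arrays left out 0 to 3422. The 2-fold limit lowers a count by construction; for the others the cause was not tested. In the limma fits a group left with 1 array was assumed to vary like the other groups, while the spread test leaves such a group out. The mean change of cytosolic ribosomal proteins in homozygotes was 0.012 after quantile normalization, where the test pointed down. Without single arrays the tricarboxylic acid list ranged from -0.069 to 0.35 in homozygotes and from -0.15 (called down) to 0.28 (called up) in the evolved strain, the respiratory list in the evolved strain from -0.0089 to 0.20, GAL1 in homozygotes from -3.95 to 0.024 and OPT2 from -0.0075 to 1.88; the cause was not tested.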

Other observations

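All tests in this part were chosen after the results had been seen.

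Genes for the synthesis of NAD from tryptophan, which share the name BNA, were higher in homozygotes than in parental arrays: 5 of 7 rose and none fell (median log2 change 0.80, camera adjusted p = 0.0124 over 144 families of at least 6 genes with a shared name; adjusted p = 0.962 with an estimated correlation). BNA2 changed by 2.33 ± 0.24 (SE), BNA6 by 0.86 ± 0.11, BNA3 by 0.86 ± 0.14 and BNA1 by 0.80 ± 0.16, while BNA7 was at -0.20 ± 0.08 and not past the threshold. The median was 0.34 without parental array 1 and 1.07 without parental array 2. Of 10 purine synthesis genes named ADE, 6 rose and none fell (median 0.35, adjusted p = 0.0124; adjusted p = 0.962 with an estimated correlation), with ADE17 at 0.86 ± 0.18 and ADE13 at 0.60 ± 0.11. The parental arrays were far apart on these genes, with signals of 2643 ± 1306 (SD, n = 2) for ADE17 and 2764 ± 838 for ADE13. The ADE median was 0.19 without parental array 1 and 0.60 without parental array 2. Of 7 protein mannosyltransferase genes named PMT, 5 fell and none rose (median -0.46, adjusted p = 0.0186; adjusted p = 0.962 with an estimated correlation). PMT2, on chromosome I, changed by -1.38 ± 0.13, and PMT4, elsewhere, by -0.50 ± 0.09. Quantile normalization and median centring left the 3 directions as they were (medians 0.79 and 0.84, 0.32 and 0.39, and -0.32 and -0.42).

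Differences in growth stage between the 8 homozygote cultures may set ribosome biogenesis genes against genes of slower growth. As a hypothesis this was tested with 3 relations across the homozygotes. The trehalose and glycogen list mean moved opposite to the ribosome biogenesis mean (Pearson r = -0.88, exact permutation p = 0.0052, adjusted p = 0.0157; Spearman rho = -0.90, exact permutation p = 0.0046, adjusted p = 0.0137), with r = -0.90 without homozygotes 8 and 6. The glyoxylate and gluconeogenesis list gave r = -0.64 (exact permutation p = 0.0838, adjusted p = 0.126; rho = -0.40, exact permutation p = 0.327, adjusted p = 0.490) and r = -0.03 without homozygotes 8 and 6, on which it rests. The mitochondrial ribosomal list gave r = -0.20 (exact permutation p = 0.646, adjusted p = 0.646; rho = -0.10, exact permutation p = 0.840, adjusted p = 0.840) and r = 0.18 without them. Across the same homozygotes the rRNA signal had r = 0.79 with the glyoxylate list, 0.34 with trehalose and glycogen and -0.14 with the mitochondrial ribosomal list. Growth itself was not measured in the values used here, and 1 of 3 relations held.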
